A study of Homo sapiens with 12 samples.

How the data were processed

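The series holds 12 samples of IMR-90 cells, a human embryonic lung fibroblast line: 9 H3K27ac libraries, 3 each from proliferating cells and from cells 2 and 10 days after 10 Gy of gamma radiation, and 3 inputs without a processed file. Libraries were grouped by the labels' description of each culture. The sample titles call both the proliferating and the day 2 libraries controls. The series design mentions irradiation or oncogene induction for the day 2 control, while the labels of these samples name irradiation only. The labels name 2 library preparation kits without saying which library had which, so a kit batch could not be examined. Per the submitters' processing notes, Bowtie 1.1.2, MACS 1.4.2 and deepTools 3.1.0 were used with the hg19 build, without the role of each.

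Each deposited file is a list of regions for 1 library, with chromosome, start, end, a name and a score. The names count the MACS peaks joined in a region. The score the authors deposited is the rank of the region in its own list: each whole number from 1 to the number of regions occurs once. The program that joined and ranked the regions, the joining distance and the use of the inputs are not given in the sources used here. No file holds reads, counts, signal or p-values, so depth is unknown and no interval from it is given. A region near the authors' limit can enter or leave a list with depth alone, and absence from a list is not absence of the mark. Because lists were called separately in each library, covered length moves with how much was called. Ranks were described within lists only.

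All regions of the 9 libraries were merged where they overlapped or touched. A consensus region was present in a library with at least 1 bp of a listed region. Coordinates are printed from 1. A region was called gained when 3 of 3 libraries of the first group and 0 of 3 of the second listed it, and lost in the reverse case; these counts were set beside those of the 10 splits of the 6 libraries. Similarity was the base-pair Jaccard index, tested over the 280 splits of the 9 libraries into 3 groups. Region number and covered length were compared by exact permutation tests, two-sided, with Benjamini-Hochberg adjustment over 24 tests of library measures. limma 3.58.1 in R 4.3.3 tested log2 of the covered kb plus 1 for 1310 consensus regions present in at least 2 libraries, with all 9 libraries in 1 fit, a mean-variance trend and Benjamini-Hochberg adjustment per comparison, at an adjusted p under 0.05. Covered length is not normally distributed where a list omits a region, so limma's p-values are approximate. Zeros shared by a whole group add no spread, so the smallest p-values can overstate the evidence. The fit estimated 0.736 prior degrees of freedom beside 6 residual ones. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

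Regions were named by a rule fixed before the data were examined, as were the tests and the alternatives unless stated. For each comparison and direction, the 10 regions with the largest difference in mean covered kb were named among those that passed both the presence rule and limma. Where a region outside this rule is named, it was chosen after its values were seen; this holds for the top-ranked regions, the shared regions and those with a day 2 course. The gene part of the plan, lists of genes and cell type markers with Fisher's exact test and the named cyclin-dependent kinase inhibitors CDKN1A, CDKN2A and CDKN2B, was not run. The files hold no gene names and the annotation at hand was of GRCh38, whose coordinates must not be mixed with hg19.

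Both procedures were tested on simulated data. For senescent against proliferating, limma over 1310 regions recovered 100% of 100 regions made present in one group and absent in the other, and 73% of 100 regions changed 2-fold in length. These regions were covered in all 9 simulated libraries before the change and stayed present at day 2. Recovery of regions that only some day 2 libraries list was not tested. Of limma's calls, 20 or 10.4% were unchanged regions, above the nominal rate. In simulated lists with 1434 regions the presence rule found all 100 gained and 100 lost regions, and 5 and 8 more by chance. The made regions met the rule by design, so finding them checks the computation and not the rule's sensitivity.

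Replicate numbers occur in all 3 groups, and nothing in the labels says that a number marks a shared culture or day. No region list shared an identical region with another. Alternatives covered the overlap that counts as present, 5 kb bins, stricter lists, the pseudocount, the filter, scaling to total length, robust moderation, a replicate block and each library left out in turn. Equal numbers of top-ranked regions, and the day 2 state, overlap and course without day 2 replicate 2, were added after the data were seen, as were the highest Jaccard index that a pair of covered lengths allows and the shuffled values for the day 2 course.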

Results

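H3K27ac, an acetylation of histone H3 found at active enhancers and promoters, was mapped by chromatin immunoprecipitation and sequencing in IMR-90, a fibroblast line from human embryonic lung. The cells were in 1 of 3 states: proliferating, 2 days after a gamma radiation dose of 10 Gy, or 10 days after that dose, when the submitters call them senescent. Each state had 3 H3K27ac libraries, so 9 libraries were compared. The 3 input libraries came without a region list and were not used here. The labels call the replicates technical, so every p-value measures the spread between these libraries, which may not come from separate cultures. Each library's file lists regions built by joining neighbouring peaks, in hg19 coordinates, with the rank of each region in its own list. The files give neither read counts nor signal, so the sequencing depth is unknown. No region was tied to a gene, because no hg19 annotation was at hand.

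Senescent libraries listed 1126 ± 22.6 regions (SD, n = 3), proliferating libraries 929.7 ± 35.6 and day 2 libraries 886.3 ± 139.7. The covered length was 66.7 ± 5.28 Mb in senescent, 48.7 ± 1.82 Mb in proliferating and 47.4 ± 17.5 Mb in day 2 libraries. The wide day 2 spread came from replicate 2, which listed 725 regions over 27.5 Mb, while replicates 1 and 3 listed 969 and 965 regions over 60.3 and 54.4 Mb. The median region length was 48.4 ± 4.30 kb in senescent, 41.8 ± 1.48 kb in proliferating and 43.8 ± 10.3 kb in day 2 libraries.

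**Figure D1:**
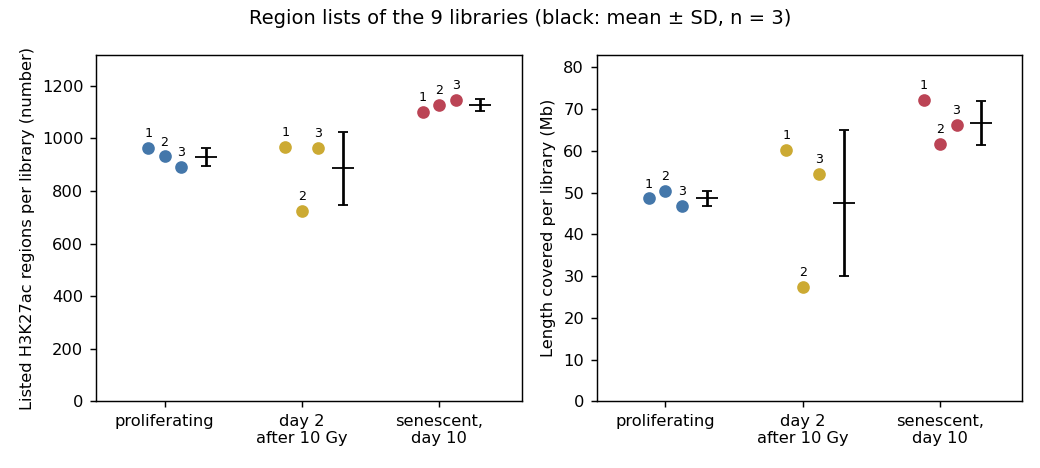
Number of listed H3K27ac regions (left axis, count) and length they cover (right axis, Mb) for each of the 9 libraries, with the replicate number above each point and the group mean ± SD (n = 3) in black. All 3 senescent libraries lie above every other library on both axes, and day 2 replicate 2 is lowest with 725 regions and 27.5 Mb.

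Merging all lists gave 1516 consensus regions over 100.1 Mb. All 9 libraries listed 485 of them, 32.0%, and these were long, with a median of 75.8 kb. A chromosome 5 region near 14140987 to 14494052 held rank 1 in 6 libraries. In senescent replicate 1 the first rank went to chromosome 6 from 56330783 to 56737137, a region of 406 kb that all 9 libraries listed in some part.

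By mean Jaccard index, proliferating and senescent libraries each resembled their own state more than any other. This index, the base pairs shared by a pair of libraries over those in either, averaged 0.699 among proliferating and 0.729 among senescent libraries. Between those states it averaged 0.510. As a percent of the highest index that their covered lengths allow, proliferating pairs reached 71.3% to 76.1% and senescent pairs 79.6% to 83.7%. Pairs across these states reached 64.9% to 74.4%, which overlaps the proliferating range. Day 2 replicates 1 and 3 shared an index of 0.703, and replicate 2 reached 0.417 and 0.454 with them. With it, the day 2 libraries averaged 0.524 among themselves, below their 0.542 with proliferating libraries. The short list of replicate 2 limits its index: it reached 91.3% and 89.8% of the highest value its covered length allows with day 2 replicates 1 and 3, 82.9% to 87.2% with proliferating and 89.0% to 89.6% with senescent libraries. The mean index within groups exceeded that between groups by 0.127, the largest difference among all 280 splits of the 9 libraries into groups of 3 (permutation test, one-sided p = 0.00357). Without day 2 replicate 2, the day 2 libraries averaged 0.572 with proliferating and 0.595 with senescent libraries. Of the highest index allowed, day 2 replicate 1 reached 70.3% to 70.9% with proliferating and 62.3% to 73.1% with senescent libraries. Replicate 3 reached 61.8% to 66.0% and 67.1% to 74.8%. Allowing for covered length, the order of the averages thus held for replicate 3 but not clearly for replicate 1.

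**Figure D2:**
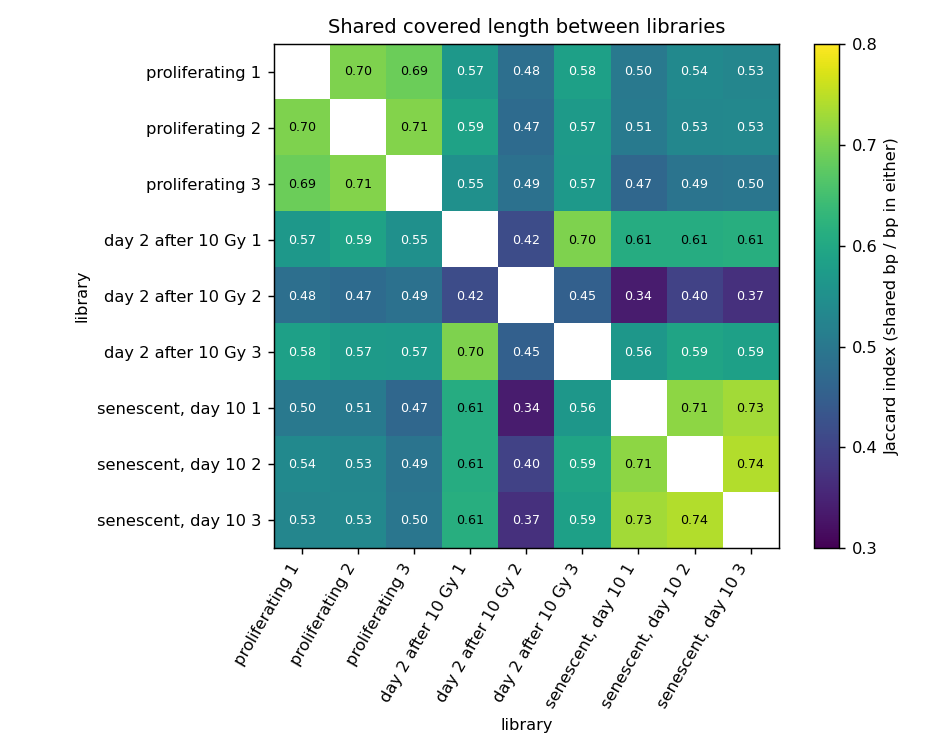
Jaccard index of covered base pairs for every pair of the 9 libraries, with libraries on both axes and the index as colour and number. Proliferating pairs range from 0.687 to 0.706 and senescent pairs from 0.715 to 0.743, while pairs across these states range from 0.466 to 0.538.

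The comparison of senescent with proliferating cells asks which large H3K27ac regions differ once irradiated cells have become senescent. All 3 senescent libraries listed 191 regions that no proliferating library listed, and 66 regions showed the reverse. With the 725 top-ranked regions of each list, a choice made after the data were seen, 90 were gained and 98 lost. Lists of equal number by themselves draw these counts towards each other, though they need not make them equal. The longest named gained region, on chromosome 3 from 98496490 to 98643515, covered 133 ± 14.6 kb (SD, n = 3) in senescent libraries and was listed at 0 kb in proliferating libraries. On chromosome 5 from 16685208 to 16825741 the senescent libraries had 123 ± 11.2 kb, and on chromosome 10 from 93336204 to 93452790 they had 113 ± 3.16 kb. No day 2 library listed either of these. Chromosome 7 from 77165313 to 77299717 held 130 ± 2.69 kb and chromosome 2 from 114615202 to 114736448 held 120.5 ± 0.620 kb, and for each 2 of the 3 day 2 libraries also had a region. The gained region listed by all 3 day 2 libraries among the 10 named was on chromosome 10 from 64892858 to 65049612, with 97.9 ± 37.0 kb in senescent libraries.

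The longest named region lost in senescent cells lay on chromosome 1 from 21555754 to 21671666, with 106 ± 11.9 kb (SD, n = 3) in proliferating libraries and 0 kb in senescent libraries. Chromosome 5 from 95220481 to 95311380 had 86.6 ± 3.11 kb and chromosome 8 from 141538162 to 141658553 had 80.1 ± 7.27 kb, and both were still present in all 3 day 2 libraries. In contrast, chromosome 9 from 15997766 to 16072116, with 72.5 ± 1.86 kb, and chromosome 4 from 129730769 to 129797482, with 64.6 ± 1.18 kb, were in no day 2 library. On average the gained regions covered 8.93 Mb of a senescent library and the lost regions 2.43 Mb of a proliferating library.

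In limma's moderated test of covered length over 1310 regions, 220 were longer and 70 shorter in senescent than in proliferating libraries at an adjusted p under 0.05. With lengths scaled to each library's total, 192 were longer and 108 shorter, and the scaling moved the median log2 change of all regions by -0.38. The 10 named gained regions had adjusted p from 6.74e-09 to 0.0350 and the 10 named lost regions from 6.74e-09 to 0.0457. The higher values belonged to regions that only some day 2 libraries listed, because the test uses a spread common to the 3 groups. The lowest belonged to regions at 0 kb in every library of 2 groups, where equal zeros add no spread. Such values reflect absence from the lists and can overstate the evidence of 3 libraries per group. The named regions were also chosen among those past limma. Leaving out any single senescent or proliferating library ended the call of 10 of these 20 regions. They included the longest named gained region, on chromosome 3, and the longest named lost region, on chromosome 1. The named gained regions on chromosome 7 and on chromosome 2 from 114615202 were also among them. Without day 2 replicate 2 those 10 stayed called, at limma adjusted p from 2.26e-08 to 0.0291. The number of longer regions fell to 144 without proliferating replicate 3. Of the 1433 regions in these 6 libraries, 282 were listed by exactly 3 of them, and a random choice of libraries would class 10% of these, 28.2, as gained or lost, against the 257 counted.

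**Figure D3:**
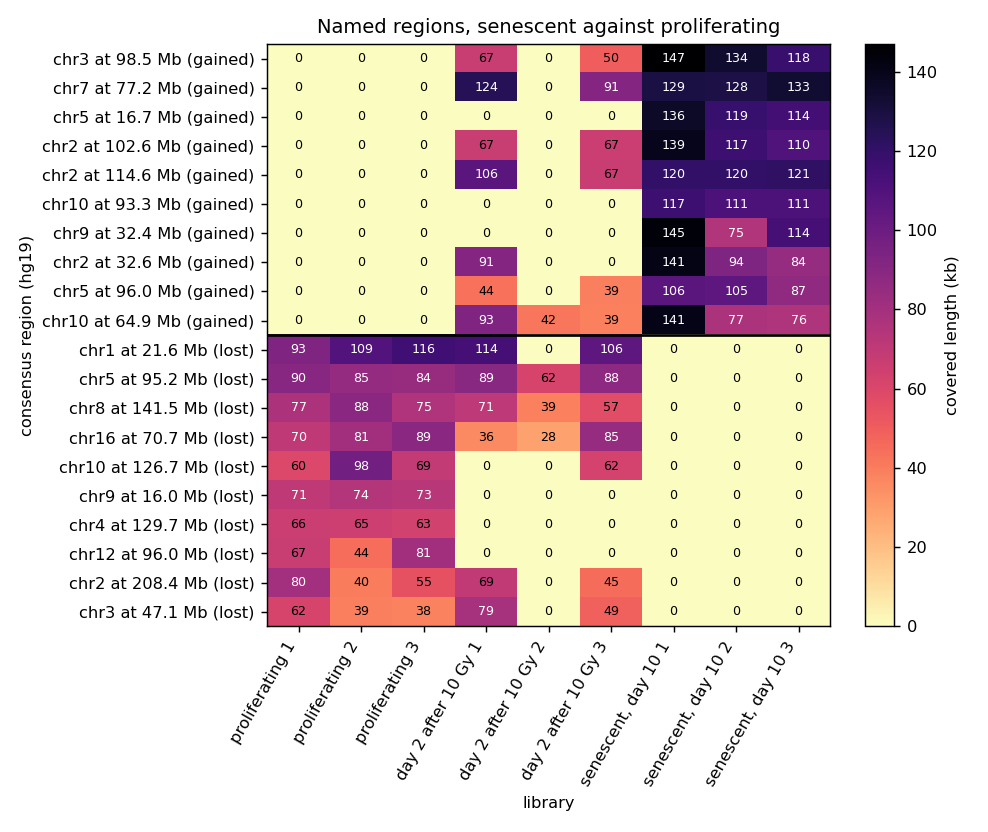
Covered length in kb (colour and number) of the 10 named gained and 10 named lost consensus regions in each of the 9 libraries, which are on the horizontal axis. Gained regions run from 97.9 to 133 kb on average in senescent libraries and lost ones from 46.2 to 106 kb in proliferating libraries, and the day 2 libraries hold some of each.

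Of the difference of 18.1 Mb in covered length between senescent and proliferating libraries, the gained regions gave 8.93 Mb and the lost regions -2.43 Mb. The 774 regions neither gained, lost nor shared by all 9 libraries gave 7.17 Mb, at 21.7 ± 2.54 Mb against 14.6 ± 1.16 Mb (SD, n = 3 each). The 485 regions listed by all 9 libraries gave 4.40 Mb, at 36.1 ± 2.10 Mb against 31.7 ± 0.884 Mb. Every senescent library exceeded every proliferating library in number of regions and covered length, in a ratio of means of 1.21 and 1.37. The exact permutation test gave p = 0.1 for each, two-sided, the smallest it allows with 3 against 3 libraries, and the Benjamini-Hochberg value over the 24 tests of library measures was 0.267. Within the 485 shared regions, limma called 30 longer and 6 shorter in senescent libraries, and 9 longer and 44 shorter after scaling to total length. The scaling lowers changes throughout by more than the median log2 change of 0.10 among these regions, so it turns the balance by construction, and no direction is given for them as a group.

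A few shared regions, picked after their values were seen, changed the same way with and without scaling and with each library left out. On chromosome 12 from 94167881 to 94213633 the covered length was 16.4 ± 0.418 kb in proliferating, 16.9 ± 1.42 kb in day 2 and 45.6 ± 0.160 kb in senescent libraries (SD, n = 3), a limma log2 change of 1.42 (SE 0.09, adjusted p = 9.82e-06). Chromosome 2 from 189898190 to 190045844 went the other way, from 141.7 ± 2.66 kb in proliferating and 143.8 ± 3.52 kb in day 2 libraries to 42.9 ± 5.99 kb in senescent libraries (limma log2 change -1.71, SE 0.09, adjusted p = 4.93e-06). Chromosome 11 from 65183106 to 65224472 shortened from 39.2 ± 0.267 kb to 21.7 ± 2.61 kb (limma log2 change -0.83, SE 0.09, adjusted p = 0.000428).

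The gained regions stood low in the senescent lists. Their median rank percentile was 68.9, where 100 is the end of the list, and 10 of 191 were in the top 25%. Lost regions stood as low in the proliferating lists, at a median of 70.6 with 2 of 66 in the top 25%. Regions in all 9 libraries had a median percentile of 27.7 in the senescent lists. The gained region with the best ranks lay on chromosome 13 from 87728697 to 87801649, at ranks 123, 109 and 117 in the senescent lists, and no day 2 library listed it. Next came chromosome 4 from 119887584 to 119975277, at ranks 173, 165 and 176 and 87.5 ± 0.222 kb, also in no day 2 library.

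The comparison of senescent with day 2 cells asks which regions were listed at day 10 and not at day 2, or the reverse. All 3 senescent libraries listed 147 regions absent from all day 2 libraries, and 20 regions showed the reverse. Of the 147, 99 were in no proliferating library and 19 were in all 3, so not all of them first appeared late. Chromosome 5 from 16685208 to 16825741 and chromosome 10 from 93336204 to 93452790 again led the gained regions, at 123 ± 11.2 and 113 ± 3.16 kb (SD, n = 3). Chromosome 9 from 32386631 to 32531586 came next, with 111 ± 34.9 kb, then chromosome 4 from 140956955 to 141084656, with 97.2 ± 34.8 kb and a region in 2 proliferating libraries. Chromosome 3 from 171488680 to 171595873, with 95.8 ± 13.1 kb, was in no proliferating library, like the first 3. Chromosome 5 from 112293876 to 112405031, with 88.4 ± 38.8 kb, was also in all 3 proliferating libraries and so was absent at day 2 alone. The regions lost by day 10 were led by chromosome 5 from 95220481 to 95311380, with 79.6 ± 15.3 kb in day 2 libraries, and chromosome 8 from 141538162 to 141658553, with 55.6 ± 16.2 kb. Chromosome 5 from 111318994 to 111348287, with 27.4 ± 3.16 kb at day 2, was listed in neither proliferating nor senescent libraries.

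limma called 160 regions longer and 20 shorter in senescent than in day 2 libraries, and 125 longer and 35 shorter after scaling to total length, which moved the median log2 change by -0.29. The named gained regions had adjusted p from 8.75e-09 to 0.0234 and the named lost regions from 2.64e-08 to 2.57e-05. Without day 2 replicate 2 the lost regions rose from 20 to 45 and those limma called shorter from 20 to 47. That removal ended the call of chromosome 4 from 140956955 to 141084656 (adjusted p = 0.0653 in limma without it) and of chromosome 4 from 54854519 to 54953795 (0.0607), as did leaving out any other single day 2 or senescent library. The 167 gained or lost regions compare with 21.9 if the 219 regions in exactly 3 of these 6 libraries fell by chance, the share being 10%. Senescent libraries exceeded all day 2 libraries in number of regions and in covered length, by means of 239.7 regions and 19.3 Mb (exact permutation p = 0.1 for each, two-sided, the smallest possible). Without day 2 replicate 2 the differences were 159 regions and 9.38 Mb (exact permutation p = 0.2 for each, the smallest possible without that library).

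The comparison of day 2 with proliferating cells addresses the early response to the dose. All 3 day 2 libraries listed 28 regions that no proliferating library listed, and 63 regions showed the reverse. Chromosome 10 from 64892858 to 65049612 led the gained regions with 57.8 ± 30.3 kb (SD, n = 3). Chromosome 4 from 48331144 to 48393225 had 50.8 ± 16.3 kb, chromosome 2 from 56065575 to 56117671 had 50.3 ± 0.985 kb and chromosome 16 from 75406026 to 75461953 had 47.6 ± 6.61 kb. All 10 named gained regions were also in every senescent library. The lost regions included chromosome 9 from 15997766 to 16072116 and chromosome 4 from 129730769 to 129797482, which stayed absent in senescent libraries. Others were present again at day 10, such as chromosome 12 from 76076599 to 76153911, with 53.8 ± 19.8 kb in proliferating libraries, and chromosome 11 from 35531214 to 35578096, with 46.0 ± 0.467 kb.

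limma called 27 regions longer and 54 shorter at day 2 than in proliferating libraries. Adjusted p ran from 2.84e-08 to 0.00123 for the named gained regions and from 2.84e-08 to 0.0457 for the named lost regions. The direction of this balance rested on day 2 replicate 2. Without it, 106 regions were gained and 69 lost, and limma called 109 longer and 59 shorter. The 146 regions in exactly 3 of these 6 libraries would give 14.6 by chance, a share of 10%, against the 91 counted. Chromosome 11 from 122502861 to 122604331, with 87.1 ± 15.2 kb in proliferating libraries, had the longest covered length of the named lost regions, but its limma adjusted p of 0.0457 became 0.0784 without that replicate. The means of region number and covered length differed by -43.3 regions and -1.26 Mb (exact permutation p = 1, two-sided). Without replicate 2 they differed by 37.3 regions and 8.69 Mb (exact permutation p = 0.2, the smallest possible without that library). No direction thus held.

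The course over the 3 states followed from these calls. Of the 191 regions gained at day 10, 99 were in no day 2 library, 51.8% (Wilson 95% interval 44.8% to 58.8%, counting regions only). All 3 day 2 libraries held 21 of them, and replicates 1 and 3 both held 65, 34.0%. Of the 66 regions lost at day 10, 32 were already absent from every day 2 library, 48.5% (36.8% to 60.3%), and 13 were still in all 3. Day 2 replicates 1 and 3 held 42.9% and 38.2% of the gained regions, and replicate 2 held 13.6%. The gained regions of both times shared 21, where independent lists would share 3.53 and unchanged groups set against the same proliferating libraries shared 1.09 in simulation. The lost regions shared 32, against 2.74 and 1.53. Without day 2 replicate 2 the shared regions numbered 65 gained, against 13.4 for independent lists, and again 32 lost. Both kinds of reference value are too low. A region that any proliferating library lists can be gained at neither time, and one that any of them lacks can be lost at neither. The independent values ignore this, and the simulation, without a group effect, makes fewer calls than the data. The proliferating libraries serve as control in both comparisons and are too few to divide, so part of the excess may come from the shared control. Its size is not decided here.

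**Figure D4:**
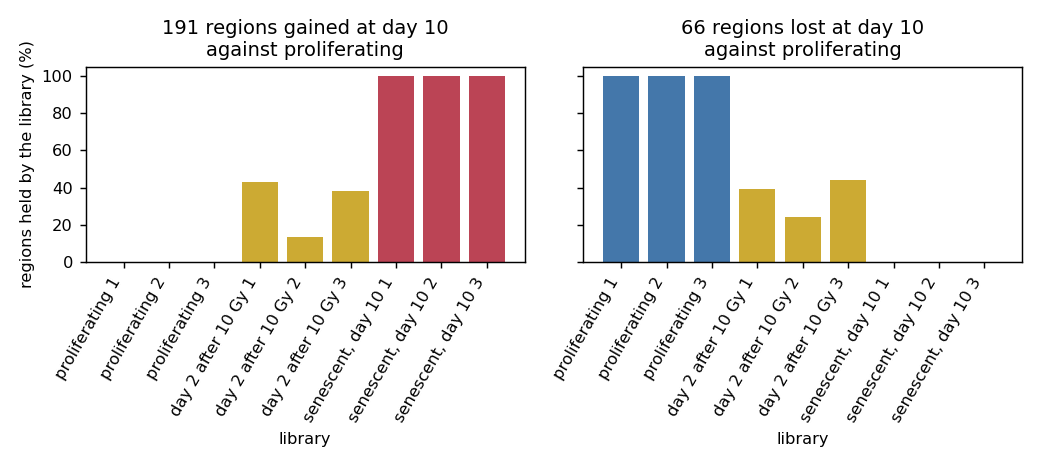
Percent of the 191 regions gained (left) and the 66 lost (right) at day 10 against proliferating that each of the 9 libraries lists, with libraries on the horizontal axis and 1 bar per library. Senescent and proliferating bars are 100% or 0% by construction, and the day 2 bars are 42.9%, 13.6% and 38.2% for gained and 39.4%, 24.2% and 43.9% for lost regions.

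In limma, 25 regions at day 2 differed from both proliferating and senescent libraries in the same direction. Both tests use the same 3 day 2 libraries, so they are not independent findings. With values shuffled over the 9 libraries, separately for each region, 100 draws gave a mean of 3.32 such regions and at most 9. This check was added after the data were seen. Separate shuffling breaks differences that span a whole library, so the draws may give too few regions. Independent lists of calls would share 7.01. Of the 25, 20 were shorter or absent at day 2 and 5 were longer, where the draws gave at most 4 and 7 and independent lists 6.60 and 0.412. The 5 thus lay within the range of the draws but above the independent value. This balance rested on day 2 replicate 2: without it 47 regions took such a course, 24 of them shorter or absent at day 2 and 23 longer, with no such draws made for that fit. Chromosome 4 from 148460878 to 148522434 covered 21.2 ± 0.796 kb in proliferating libraries, 0 kb at day 2 and 59.0 ± 0.813 kb in senescent libraries (SD, n = 3). Chromosome 3 from 66448250 to 66496577 went from 42.5 ± 1.73 kb to 0 kb and to 42.7 ± 4.77 kb. The one with the longest covered length, on chromosome 3 from 149241686 to 149380485, was listed throughout and shortened from 134.6 ± 1.95 kb to 92.2 ± 4.74 kb before returning to 130.1 ± 1.76 kb. The opposite course was seen on chromosome 7 from 137258955 to 137277555, with 17.4 ± 1.12 kb at day 2 and 0 kb in the other states. All 25 kept both calls with each of the 9 libraries left out in turn, and 24 kept them after scaling.

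**Figure D5:**
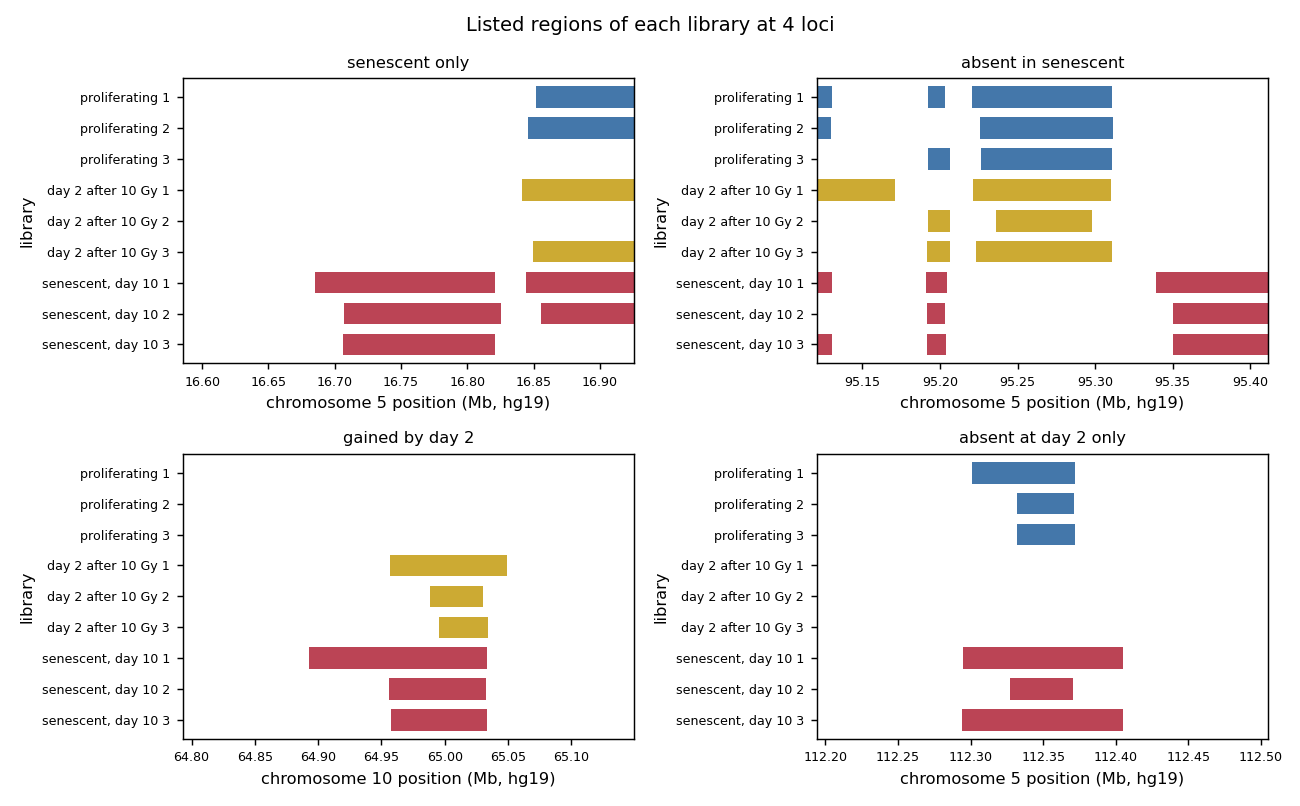
Listed regions of each library (1 row per library, coloured by state) at 4 loci, with hg19 position in Mb on the horizontal axis: a region of senescent libraries alone, one in all libraries but the senescent, one gained by day 2 and one absent at day 2 alone. Each has the longest mean covered length among regions of its presence pattern; they lie on chromosome 5 from 16685208, chromosome 5 from 95220481, chromosome 10 from 64892858 and chromosome 5 from 112293876.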

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

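The tests of fewer peaks in day 2 replicate 2, of equal top-ranked lists, of shuffled values and of the splits for gained and lost regions were chosen after the results they bear on were seen.

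Covered length differed between day 10 and day 2 after irradiation in 180 regions by limma, which marks a difference between 2 times under the same treatment. Among them, 25 differed at day 2 from proliferating libraries too, in the same direction. Both tests share the day 2 libraries. Values shuffled separately for each region gave at most 9 in 100 draws, which may be too few, since differences that span a library are not kept. The peak numbers in the region names, which are no part of the compared regions, reached a mean of 67390 in senescent libraries, above the 54543 of proliferating libraries (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 libraries allow; 0.267 after Benjamini-Hochberg adjustment over 24 tests). The day 2 mean was 54649 (exact permutation p = 0.2 against senescent), and day 2 replicate 1, at 66123, exceeded senescent replicate 3, at 65800.

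Gained regions outnumbered lost ones in senescent against proliferating libraries, 191 to 66. With the same 725 top-ranked regions taken from every library, the counts were 90 and 98, a ratio of 0.918. Equal numbers by themselves draw the counts of gained and lost regions towards each other, but need not make them equal. Day 2 against proliferating gave 30 gained and 48 lost with such lists. A ratio this low is what longer senescent lists predict, but equal lists lower an excess of gains whatever its cause. The ratio thus does not decide whether the longer senescent lists gave the excess. Gained regions ranked in the lower part of the lists, at a median percentile of 68.9 (lost regions 70.6 in theirs), between the bounds set for a list-end effect and against it, so that explanation cannot be told apart from a spread of ranks. The listed regions held a mean of 14244 peaks in senescent and 11812 in proliferating libraries, where the highest peak numbers averaged 67390 and 54543. The lists thus hold only part of the numbered peaks, and covered length is not the whole acetylated length. A wider acetylated genome in senescent cells and deeper or better enriched senescent libraries would both lengthen the lists. Both stay open, as does where the authors' limit fell in each list, since signal and depth were not analysed here.

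Day 2 replicate 2 listed fewer and shorter regions than any other library. It may hold a subset of called peaks from a shallower or less enriched library, since 96.8% of its length lay inside the regions of the other day 2 libraries and its peak number was 75.8% of the lowest other. Its length also lay 94.9% inside the proliferating and 95.1% inside the senescent lists, so the overlap alone does not place it. This library held 8.70% of the regions that all proliferating and neither other day 2 library listed (6 of 69). It held 26.4% (28 of 106) of those both other day 2 libraries and no proliferating library listed (Fisher's exact test, two-sided p = 0.00346). Its list held 44.0% of all consensus regions, so its shortness can lower both shares, and neither share decides alone. The higher share of the day 2 kind argues against a proliferating library under a day 2 label. The kinds were not matched for rank, and Fisher's test treats regions as independent. No biological explanation was tested for it.

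For splits of the 6 libraries of a comparison, 10 are too few for a share under 0.05, and in each only 1 split, the real one, reached the real count. Gained and lost regions numbered 257 for senescent against proliferating, with 5 in the highest other split, 167 against 11 for senescent and day 2, and 91 against 14 for day 2 and proliferating. limma's calls numbered 290, 180 and 81, with 3, 10 and 15 in the highest other split. Over all 9 libraries, limma's F test called 222 of 1310 regions. Of 100 splits, 1, the real one, reached that number, and the highest other gave 135. This share is the smallest that 100 splits allow, so a chance division of the libraries is argued against for this test but not excluded.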

How the results depend on the processing

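Values are given in the order senescent against proliferating, senescent against day 2, day 2 against proliferating, gained or longer before lost or shorter. The gene list overlap and its alternatives were not run, for want of an hg19 annotation. In 5 kb bins the presence rule gave 2275 and 488, 1482 and 114, 139 and 470 bins, and limma 2250 and 495, 1248 and 114, 147 and 391, since bins are smaller and more numerous. With equal numbers of the longest regions, the rule gave 98 and 85, 52 and 30, 18 and 36, and limma 112 and 84, 57 and 24, 16 and 27. In the longest 50% of each list the rule gave 75 and 21, 46 and 5, 1 and 17, and limma 77 and 18, 46 and 4, 1 and 10, with fewer regions to count. Equal numbers of top-ranked regions, chosen after seeing the data, gave 90 and 98, 53 and 40, 30 and 48, and in limma 116 and 99, 63 and 34, 26 and 43. Presence in at least 2 of 3 libraries gave 283 and 112, 220 and 57, 115 and 120. Scaling to total length gave 192 and 108, 125 and 35, 31 and 59 in limma. The cause of these shifts beyond the number of units was not tested.

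With 1 library left out, the day 2 minus proliferating difference ran from -84.7 to 37.3 regions and from -7.69 to 8.69 Mb, and it reversed without day 2 replicate 2. The senescent minus day 2 difference ran from 159 to 281 regions and from 9.38 to 25.8 Mb, lowest without that replicate. The ranges of counts were 21 to 45 lost regions for senescent against day 2, 31 to 106 gained for day 2 against proliferating, 144 to 263 longer in limma for senescent against proliferating, 20 to 47 shorter for senescent against day 2 and 26 to 109 longer for day 2 against proliferating. All upper values of these counts came without day 2 replicate 2, and the 144 without proliferating replicate 3. The remaining counts of gained, lost, longer and shorter regions stayed within 1.5 times under each removal.

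The replicate numbers do not pair the libraries: of 9 same-number pairs, 1 had a correlation of deviations over 0.1, the range was -0.0507 to 0.106, and 3 of 9 libraries were closest to their own number. With a replicate block limma called 144 and 49, 139 and 20, 26 and 53. The presence rule has no p and is unmoved by a block. The similarity difference of 0.127 gave a permutation p of 0.0278 over 36 block-wise splits. For the 60 named values, 804 of 900 alternative values kept their call, 96 lost it, 81 of them with a library left out and 10 with the block, and 0 reversed. Region absence near the end of a list is limited by a depth that is unknown.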

Other observations

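Of the tests here, all were set before their result was seen.

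Gained and lost regions were spread over the chromosomes unequally in number. Chromosome 4 held 19 gained among 73 regions of the senescent and proliferating libraries, and chromosome 19 held 0 of 35, which allows a share of up to 8.57%. Gained regions were 13.3% of all. A wider spread between chromosomes than random placement was not established, with a permutation p of 0.096 for gained and 0.194 for lost regions.

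Regions gained in senescent cells lay next to each other on the genome more often than random placement gave: 35 neighbouring pairs against a mean of 24.9 with shuffled labels (central 95% from 17 to 34, one-sided permutation p = 0.0163). Shuffling within chromosomes gave a permutation p of 0.0293, so an unequal share between chromosomes does not account for it. Lost regions formed 4 such pairs against 2.94 by chance (permutation p = 0.339). Labels were shuffled over all 1433 regions, including those that proliferating libraries list, which cannot be gained. If regions open to gain lie near each other, gained pairs would exceed this reference without any grouping of the gains themselves. Grouping among the regions open to gain was not tested. Neighbouring gained pairs were separated by a median of 569 kb, against 724 kb for neighbouring regions in general. A candidate explanation is that some gains arise in wide domains, and differing joining of peaks in a domain is another; neither was tested further, and both tests rest on the same 191 regions.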
